A study of Mus musculus with 7 samples.

How the data were processed

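Total RNA came from osteocyte-enriched long bone of 4 control and 3 Dmp1-Cre Mbtps1 knockout male mice. Per the labels' protocols, 30 ng of RNA per sample was converted to biotin-labelled cDNA with a NuGEN kit. The deposited values are probe set intensities on a linear scale, 1 column per array. PLIER and Affymetrix Expression Console 1.4 are named in the submitters' processing notes, without their settings. Background correction, any normalization between arrays and the genome build are not given in the sources used here. The array medians differ (87.3 to 107.7), so the deposited intensities were not left quantile-normalized at the probe set level. The smallest values lie near 0. Groups and replicate numbers were taken from the labels. The labels call the mice littermates but do not say which shared a litter.

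Gene names came from the platform's probe annotation, with symbols checked by Entrez identifier against RefSeq of GRCm38.p6, which changed none of them. Of the probe sets, 21789 name 1 gene, 1621 name several and 12146 are unnamed here. Only those naming 1 gene were used. They cover 19938 genes, and 91 of these probe sets have no position in that assembly. No coordinates are given, because the build of the deposited data is not stated. Each gene was represented by its probe set with the highest mean. Probe sets under the 30th percentile of mean log2 signal (log2 6.42, intensity 69.7) were left out, which left 13938 genes. Of these, 739 had 2 or more probe sets above the filter, and for 212 the probe sets had opposite signs.

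Intensities were transformed as log2(intensity + 16), with no further normalization between arrays. Knockout was compared with control in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean-variance trend and no covariates, leaving 5 residual degrees of freedom, or 12.6 with those borrowed from other genes. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. A looser count took an unadjusted p under 0.05 and at least 1.5-fold. The 24 gene lists held 436 genes, of which 399 were named by a probe set and 355 were measured after the filter, and no gene was on more than 1 list. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists. Camera compares a list with the other genes. Beside it stand camera with a correlation estimated per list, fry, and a two-sided exact permutation test of the list means over the 35 splits of 7 arrays into 4 and 3, using the absolute difference of means. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

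Named genes followed a rule written before the data were examined. They are Mbtps1, the 12 lower and the 12 higher genes with the smallest p whose groups do not overlap (no gene passed the adjusted threshold, so all were filled in this way), and up to 4 members with the smallest p in each list. Clone names, gene model numbers and small RNA genes were skipped in the first part. Further list members are named where they passed over the list alone or where the list's purpose rests on them, and these were chosen after their values were seen.

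The tests were run on simulated data with the real means and residual spreads of 13938 genes, 200 of them changed. The limma comparison of knockout and control recovered 24% of genes changed 1.5-fold, 85.5% at 2-fold and 100% at 4-fold. With no change, 5.34% of genes had an unadjusted p under 0.05. The simulated genes were independent, which real genes are not. The 200 were drawn at random, so genes with a large spread, such as Atf3 (SE 0.34) and Mepe (SE 0.32), were not counted apart. In the real data 24 genes were at least 2-fold lower and 1 at least 2-fold higher at an unadjusted p under 0.05, and none passed the adjusted threshold.

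Alternatives written before the data were examined were other filters and offsets, quantile normalization, median centring, other variance models, array weights, a replicate block, muscle or erythroid list means as covariates, the mean of probe sets, other list tests and leaving out each array. An offset of 16 was listed as an alternative for log2 deposits and is the main setting here. Added after seeing the data were leaving out controls 3 and 4, the first principal component as a covariate, unmoderated variances, and the counts of list members under all settings.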

Results

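Gene expression was measured in osteocyte-enriched long bone of male mice aged 39 to 41 weeks. Osteocytes are the cells embedded in mineralized bone matrix. Marrow had been removed, and the bone pieces had been digested with collagenase and extracted with EDTA in 4 rounds before RNA was isolated. Knockout mice carried a deletion of Mbtps1 driven by Dmp1-Cre, a recombinase line active mainly in osteocytes and late osteoblasts. Mbtps1 encodes site-1 protease (S1P), a Golgi protease that cleaves the membrane-bound transcription factors SREBP and ATF6. Littermates served as controls. There were 4 control arrays and 3 knockout arrays, numbered as in the labels, each an Affymetrix whole-transcript array. The median intensity per array lay between 87.3 (control 3) and 107.7 (control 4). The small number of arrays limits the precision of every value. All means are given as intensity ± SD over 4 controls and 3 knockouts. Log2 fold changes (knockout minus control, log2 of intensity + 16) have their standard error (SE) and come from limma, and on this scale changes of low-signal genes are understated.

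The arrays did not separate first by genotype. The first principal component held 53.1% of the variance and had 2 controls at its ends, control 4 at -38.0 and control 3 at 25.5, with the 3 knockouts between -3.7 and 7.7. Its scores followed the first quartile of intensity per array (Pearson correlation -0.877). That quartile was 61.0 in control 4 and 40.5 in control 3. The second component held 22.5%, and on it the knockouts scored 4.4 to 17.0 and the controls -16.8 to -0.25. Pearson correlations between arrays ran from 0.888 to 0.983, and control 4 had the lowest mean correlation with the others (0.918). No pair of arrays shared more than 1 identical probe set value. Xist was low, and the Y-linked genes Eif2s3y and Kdm5d were measured, on all 7 arrays, as the male label requires. Genes of marrow cells had high signal in both groups. The neutrophil gene S100a9 read 7522 ± 152 in controls and 5863, 7201 and 6973 in knockouts 1 to 3. Ngp, another neutrophil gene, read 4424 ± 119 in controls and 3268, 4223 and 3938 in knockouts 1 to 3. In both genes every knockout lay under every control. Of the 18 measured neutrophil markers, 7 had log2 fold changes below 0 and 11 above 0. Levels of different probe sets do not compare as amounts of RNA.

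**Figure D1:**
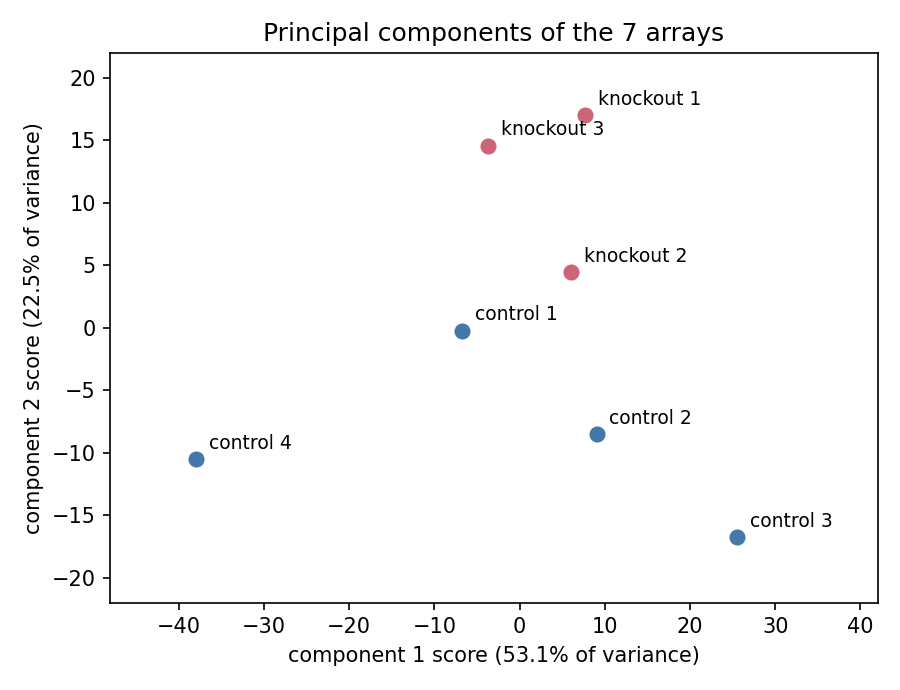
Scores of the 7 arrays on the first principal component (x axis, 53.1% of variance) and the second (y axis, 22.5%), computed from log2(intensity + 16) of 13938 genes; blue points are controls and red points knockouts. Control 4 and control 3 lie at the ends of the first component, and the knockouts lie above the controls on the second.

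The targeted gene was examined first. Mbtps1 read 149 ± 12.9 in controls and 125 ± 24.9 in knockouts, a log2 fold change of -0.23 (SE 0.14). This difference did not pass the test (limma adjusted p = 0.807; two-sided exact permutation p = 0.20 over the 35 splits of the arrays, which can give no p below 0.0286). Knockouts 1 and 2 read 115 and 107, below every control (131 to 162), whereas knockout 3 read 154, within the control range. Without knockout 3 the log2 fold change was -0.37, and without knockout 2 it was -0.14. In 1 of the sets with an array left out, Mbtps1 was lower at an unadjusted limma p under 0.05, but in none did it pass the adjusted threshold. A single probe set names Mbtps1, and which of its exons that probe set reads was not analysed here, so the value does not check the genotype labels. The RNA also came from cells in which Dmp1-Cre is not mainly active.

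To ask which genes differ between knockout and control bone, 13938 genes were compared. No gene passed a Benjamini-Hochberg adjusted p of 0.05 in limma, and the smallest adjusted p was 0.0539. At an unadjusted p under 0.05 there were 904 genes (6.49%), 526 higher and 378 lower in knockout bone. This count was 325 without knockout 1, 430 without knockout 3, 1419 without control 3 and 1803 without control 4. With a 1.5-fold minimum added, 120 genes remained, 113 lower and 7 higher. Without control 4 these were 102 genes, 67 lower and 35 higher, and without control 2 there were 199. Leaving out control 4 gave 5 genes past the adjusted threshold, and leaving out knockout 2 gave 1. Of all genes, 1113 (7.99%) had groups that did not overlap, against 5.71% on average over the 35 splits. How far this share varies between splits was not computed, so the 2 shares do not show an excess over chance. The median log2 fold change over all genes was 0.07, and it was 0.04 after quantile normalization and 0.01 after median centring.

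The 12 lower genes with the smallest p among those whose groups did not overlap were Lox, Ptprz1, Phex, Ccdc3, Klf4, Egr2, Bgn, Atf3, Irx5, Egr1, Fosb and Jun. They are given as values, since none passed over all genes with all arrays. Without control 4, Lox (adjusted p = 0.0179), Ptprz1 (0.00674) and Phex (0.0179) passed, and so did Tpbg (log2 fold change -0.93, adjusted p = 0.0480), named after its values were seen. Lox, a cross-linking enzyme of collagen, read 170 ± 17.1 in controls and 93.7 ± 1.04 in knockouts (log2 fold change -0.76, SE 0.12, adjusted p = 0.165). Bgn, the matrix proteoglycan biglycan, read 1746 ± 219 and 1119 ± 105 (log2 fold change -0.63). Ccdc3 read 284 ± 55.5 and 147 ± 36.6 (-0.88), and Egr2 read 347 ± 124 and 146 ± 26.4 (-1.11).

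The 12 corresponding higher genes were C2cd4b, Mocs3, Gsc2, Tcf15, Sox10, Ucn2, Bok, Tspan10, Usp29, Gjd3, Foxe3 and Kcnk12, most of them with low signal. C2cd4b read 61.0 ± 8.69 in controls and 167 ± 40.9 in knockouts (log2 fold change 1.24, SE 0.16, adjusted p = 0.0539). It was higher in 3 of 3 knockouts than in any control, which the rule for naming genes requires. Its control level lay under the intensity of the low-signal filter (69.7). Its adjusted p was 0.00674 without control 4, 0.0349 without knockout 2 and 0.514 without knockout 1, and over all settings run it lay between 1.49e-04 and 0.657. Mocs3, which acts in molybdenum cofactor synthesis, read 119 ± 14.9 and 204 ± 45.6 (log2 fold change 0.69). The remaining 10 had log2 fold changes between 0.44 and 0.60.

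Among 24 gene lists fixed before the data were examined, the osteocyte markers were lower in knockout bone as a set. Camera with a preset inter-gene correlation gave an adjusted p of 8.73e-12, but the adjusted p was 0.332 with an estimated correlation. Of 13 measured members, 8 fell when adjusted over the list alone, none rose, and none passed over all genes. Mepe, a matrix phosphoglycoprotein, read 1484 ± 854 in controls and 534 ± 168 in knockouts (log2 fold change -1.35, SE 0.32). Phex, an endopeptidase that controls phosphate handling, read 694 ± 297 and 264 ± 52.7 (-1.28, SE 0.25). Ptprz1, a receptor phosphatase, read 215 ± 115 and 66.2 ± 10.96 (-1.39, SE 0.26). Dmp1 (-1.25), the Wnt inhibitors Dkk1 (-1.20) and Sost (-1.15), the transcription factor Irx5 (-0.91) and the gap junction gene Gja1 (-0.53) were the other 5. Tnfsf11, which encodes RANKL, had a log2 fold change of 0.30 and Fgf23 one of 0.25, and neither passed. Cd44 (-0.23), Pdpn (-0.08) and Capg (0.16) did not pass either.

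The osteocyte list mean was 8.79 ± 0.43 in controls and 8.12 ± 0.14 in knockouts on the log2 scale, and the groups did not overlap. The two-sided exact permutation p of the list means was 0.0571, or 0.686 adjusted over the 24 lists. The count of 8 went to 0 when each gene kept its own unmoderated variance, with a smallest adjusted p of 0.0679 over the list. Control 4 had the highest osteocyte list mean (9.42, the other controls 8.48 to 8.72) together with the lowest erythroid (8.83), B cell (7.45) and cell cycle (8.68) list means of the 7 arrays. Without control 4 the same 8 genes fell and Tnfsf11 and Fgf23 rose over the list alone.

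**Figure D2:**
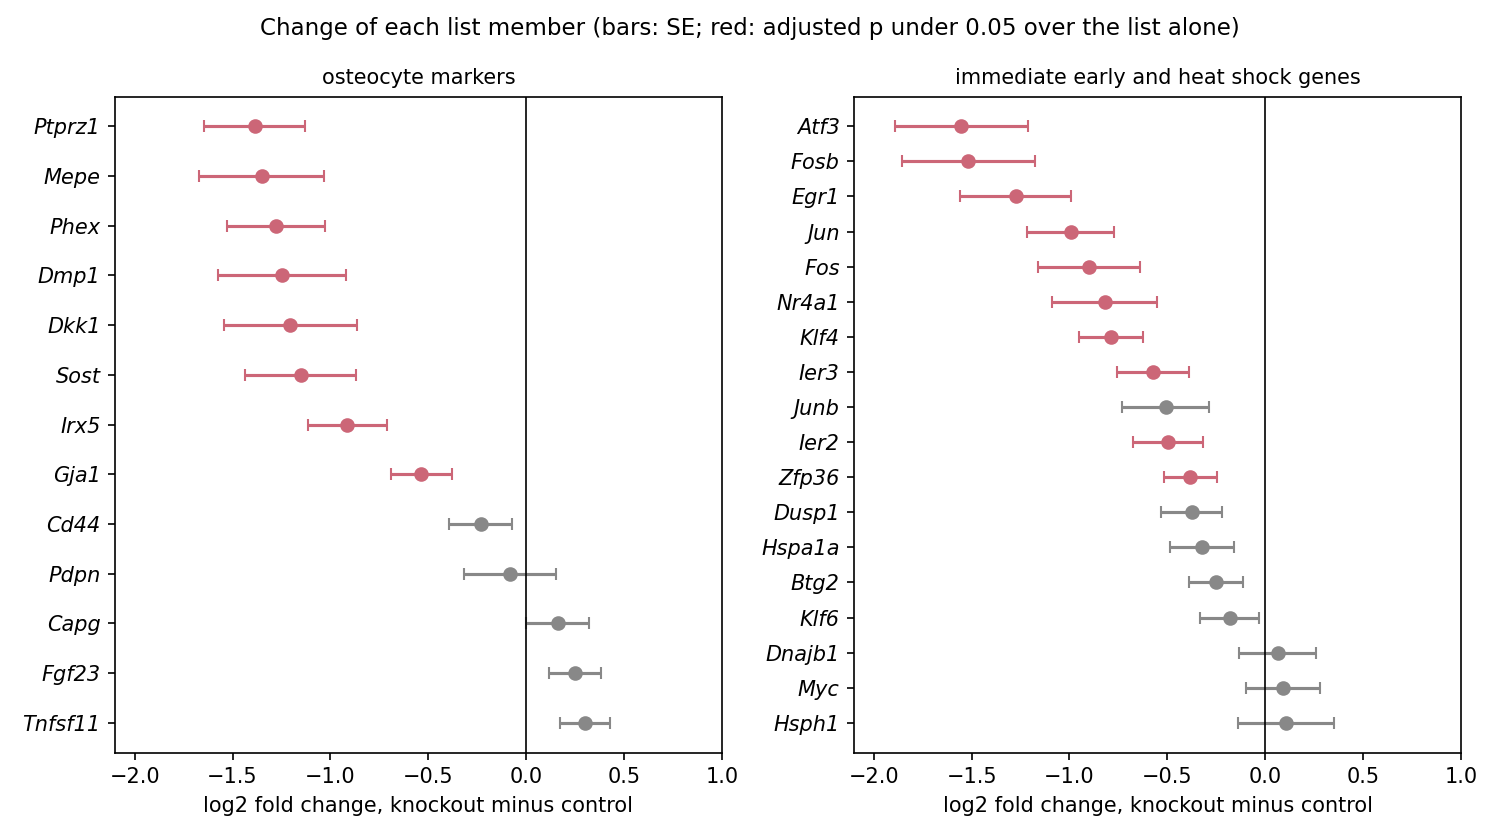
Log2 fold change (x axis, knockout minus control, log2 of intensity + 16) of each measured member of the osteocyte list (left) and the immediate early and heat shock list (right); points are limma estimates over 4 controls and 3 knockouts, bars are SE, and red marks an adjusted p under 0.05 over the list alone. In the osteocyte list 8 of 13 members are red and all of these lie below 0; in the other list 10 of 18 are red and all lie below 0.

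The list of immediate early genes, which cells induce within minutes of a stimulus, and heat shock genes was also lower as a set. Camera gave an adjusted p of 3.48e-20 with the preset correlation, and the adjusted p was 0.231 with an estimated correlation. Of the 18 measured members of the immediate early and heat shock list, 10 fell when adjusted over the list alone and none rose, and none passed over all genes. Atf3 read 522 ± 290 in controls and 147 ± 21.9 in knockouts (log2 fold change -1.55, SE 0.34). Fosb read 893 ± 481 and 266 ± 26.5 (-1.52, SE 0.34), Egr1 825 ± 322 and 318 ± 88.2 (-1.27, SE 0.28), and Jun 530 ± 154 and 253 ± 59.1 (-0.99, SE 0.22). Fos (-0.90), Nr4a1 (-0.82), Klf4 (-0.79), Ier3 (-0.57), Ier2 (-0.50) and Zfp36 (-0.38) also fell. The 3 heat shock members had log2 fold changes of -0.32 (Hspa1a), 0.11 (Hsph1) and 0.06 (Dnajb1) and did not pass. The list mean was 8.87 ± 0.24 in controls and 8.28 ± 0.20 in knockouts. The groups did not overlap, but only narrowly, with control 2 at 8.53 and knockout 2 at 8.50. The exact permutation p of the list means was 0.0571, or 0.686 adjusted over the 24 lists. The count of 10 became 5 without knockout 1, 6 without knockout 3 and 0 with unmoderated variances.

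**Figure D3:**
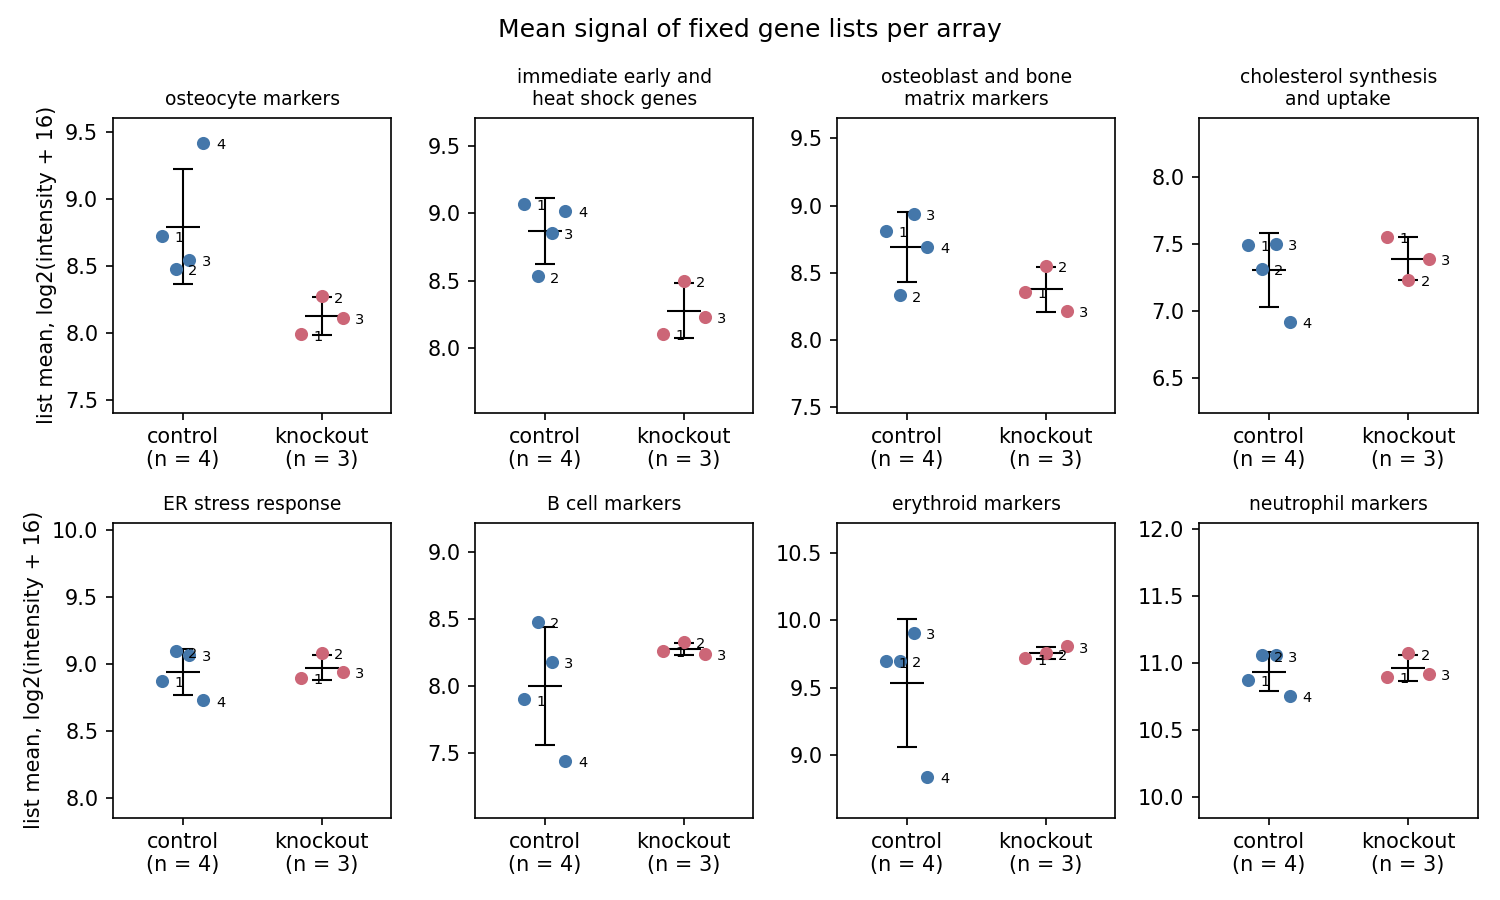
Mean log2(intensity + 16) per array (y axis) of the measured members of 8 fixed gene lists, on y axes of equal span; small numbers are replicate numbers, horizontal bars are group means and whiskers SD (4 controls, 3 knockouts). Knockout arrays lie below all controls in the osteocyte and the immediate early panels, and control 4 stands apart from the other controls in the osteocyte, cholesterol, B cell and erythroid panels.

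Osteoblast and bone matrix markers were lower as a set by a smaller amount. The camera adjusted p was 1.56e-08 with the preset correlation, and the adjusted p was 0.332 with an estimated correlation. Of 14 measured members, 12 had negative log2 fold changes, and 1 fell when adjusted over the list alone. That gene was Postn, the matrix protein periostin, at 422 ± 95.6 in controls and 231 ± 63.2 in knockouts (log2 fold change -0.83, SE 0.20). Serpinf1 (-0.51), Sp7 (-0.52, and -0.29 without control 4) and Dlx5 (-0.61, and -0.32 without control 4) did not pass, nor did Col1a1 (-0.19) and Col1a2 (-0.31), the chains of type I collagen. The list mean differed by -0.32, and the groups overlapped (exact permutation p of the list means = 0.143). Postn did not pass over the list without knockout 1 or without knockout 3, nor with unmoderated variances, and 7 members passed without control 2 and 2 without control 4.

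Of 10 Wnt pathway genes, 2 fell when adjusted over the list alone. Wif1, a secreted Wnt inhibitor, read 181 ± 53.5 and 108.3 ± 17.5 (log2 fold change -0.64, SE 0.18). Tnfrsf11b, the RANKL decoy receptor osteoprotegerin, read 236 ± 81.7 and 137 ± 39.9 (-0.70, SE 0.22). Neither passed without control 1, knockout 1 or knockout 3, nor with unmoderated variances. The set did not pass camera (adjusted p = 0.228), and its median (0.08) and mean (-0.07) had opposite signs, with camera pointing down.

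The S1P pathway was examined next, since the deleted protease acts in it. Its 14 measured components and substrates were lower as a set (camera adjusted p = 0.00419 with the preset correlation, adjusted p = 0.332 with an estimated correlation). The targeted gene Mbtps1 (log2 fold change -0.23) is itself among the 14, and the set was not tested without it. The list mean differed by -0.14 (exact permutation p of the list means = 0.143) and the median was -0.05. There were 8 members below and 6 above 0, and no member passed over the list alone. Without control 2, 3 members fell, without control 3, 2 fell and 1 rose, and without control 4, 1 fell. Insig2, which holds SREBP in the endoplasmic reticulum, read 387 ± 170 in controls and 205 ± 12.5 in knockouts (log2 fold change -0.79, SE 0.23). Fam20c, the kinase of secreted phosphoproteins, read 179 ± 58.6 and 110 ± 16.2 (-0.59, SE 0.19), and Creb3l2 read 130 ± 16.9 and 95.6 ± 14.2 (-0.39, SE 0.14). Srebf1 (-0.04) and Srebf2 (0.16), which encode SREBP, and Atf6 (0.09) did not pass either.

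Target genes of the factors that S1P cleaves did not pass the tests, and neither did genes of lysosomal proteins. The RNA came from bone pieces that also held marrow cells, where Dmp1-Cre is not mainly active. A change confined to osteocytes could be diluted there, so these values do not decide whether target genes changed in osteocytes. Of 17 cholesterol synthesis and uptake genes none passed over the list, with a median log2 fold change of 0.07 and a camera adjusted p of 0.665. Pmvk (0.23), Mvd (0.20), Mvk (0.20) and Nsdhl (0.15) had the smallest p. With each array left out they ranged from 0.13 to 0.34, 0.11 to 0.26, 0.12 to 0.28 and 0.03 to 0.24, in this order. Camera's direction relative to the other genes turned without control 4 (adjusted p = 0.158), where the list mean difference was -0.04, and without knockout 1 (0.522), where it stayed above 0 (0.0042). None of 17 fatty acid synthesis genes passed over the list (median 0.03, camera adjusted p = 0.914), but without control 4 Pnpla3 rose and Scd1 fell over the list alone. Pnpla3 (0.45), Mid1ip1 (0.37) and Elovl6 (0.36) were above and Scd1 (-0.59) below the control level, and a second probe set of Mid1ip1 gave -0.14. Elovl6 ranged from 0.24 to 0.44 and Scd1 from -0.87 to -0.34 with each array left out. Scd1 read 1899 and 1607 in controls 2 and 3, but 822 and 615 in controls 1 and 4. The latter lay within the range of knockouts 1 to 3 (647, 569 and 1083). The adipocyte marker Cidec was also highest in controls 2 and 3 (249 and 276). Of 24 genes of the endoplasmic reticulum stress response none passed (median 0.06, camera adjusted p = 0.665), with Dnajb9 at -0.48 and Sdf2l1 at 0.27. Dnajb9 ranged from -0.61 to -0.40 and Sdf2l1 from 0.14 to 0.35 with each array left out. None of 22 lysosomal genes passed (median 0.02, camera adjusted p = 0.458). For the last 2 lists camera, which compares a list with the other genes, pointed down while the median and the mean were above 0.

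B cell markers and cell cycle genes were higher in knockout bone as sets, and control 4 had the lowest mean of the 7 arrays in both lists. The camera adjusted p of B cell markers was 0.00721 with the preset correlation, and the adjusted p was 0.809 with an estimated correlation. For cell cycle genes these were 0.0462 and an adjusted p of 0.949. The exact permutation p of the list means was 0.371 for B cell markers and 0.800 for cell cycle genes. B cell markers had a list mean of 8.003 ± 0.44 in controls and 8.28 ± 0.05 in knockouts, with 15 of 16 members above 0, and none passed over the list alone. Without control 2 the difference was 0.44 and 5 members rose over the list alone (Cd79b, Fcrla, Pax5, Rag1 and Vpreb3). Vpreb3, part of the precursor B cell receptor, had a log2 fold change of 0.63 and Pax5, which sets B cell identity, one of 0.40. The B cell adjusted p was 0.399 without control 4 (difference 0.09 in place of 0.28), 0.0547 without control 1 and 0.0694 without knockout 2. Of 25 cell cycle genes, 24 were above 0 and none passed (Mcm2 0.39 and Aurkb 0.28, or 0.16 and 0.07 without control 4). The cell cycle difference went from 0.18 to -0.01 without control 4 (adjusted p = 0.375) and to 0.28 without control 3, and the call ended without knockout 2 (0.0981) and knockout 3 (0.0554) too.

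Interferon-stimulated genes were higher as a set (median 0.21, camera adjusted p = 0.0466 with the preset correlation, adjusted p = 0.796 with an estimated correlation), and none of 13 passed over the list. The exact permutation p of the interferon list means was 0.114. Rsad2 had a log2 fold change of 0.54 (0.31 to 0.68 with each array left out) and Oasl1 one of 0.38 (0.29 to 0.45). The call ended in 5 of the 7 sets with 1 array left out, without control 2 (0.116), control 3 (0.103), control 4 (0.123), knockout 1 (0.2995) or knockout 2 (0.0981). Erythroid markers (13 members, median 0.23, camera adjusted p = 0.0715) and megakaryocyte and platelet markers (9 members, median 0.36, adjusted p = 0.0841) did not pass, nor did T and NK cell (0.15, adjusted p = 0.255), neutrophil (0.01, adjusted p = 0.422) and macrophage and monocyte markers (0.06, adjusted p = 0.458). Erythroid markers passed as higher after quantile normalization (0.00986), at the 50th percentile filter (0.0464), and without control 1 (0.0287), control 2 (0.0140), control 3 (0.00346) or knockout 1 (0.0135). Megakaryocyte and platelet markers passed as higher after quantile normalization (0.00986) and without control 2 (0.0369), control 3 (0.00436) or knockout 3 (0.00287), and without control 3, Gp5, Gp9, Itga2b and Treml1 rose over the list alone. Without control 4 the megakaryocyte difference was 0.09 in place of 0.29 (adjusted p = 0.754). Macrophage and monocyte markers passed as lower without control 4 (0.0308), with array weights (0.0246) and with a replicate block (0.0291). The block takes out control 4 too. Kel (0.34), Treml1 (0.56), Cd4 (0.38), Ngp (-0.22) and Ccr2 (-0.20) had the smallest p of these 5 lists. With each array left out they ranged, in this order, from 0.10 to 0.45, 0.36 to 0.75, 0.23 to 0.52, -0.30 to -0.12 and -0.30 to -0.07. For the neutrophil list camera pointed down while the median and mean were above 0, and for the macrophage list its direction and the mean were below 0 and the median above 0.

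Adipocyte markers were lower as a set (camera adjusted p = 0.00459, adjusted p = 0.459 with an estimated correlation), with a list mean difference of -0.21, and none of 10 passed over the list alone. The difference was -0.34 without control 4 and -0.14 without control 2 or control 3. With all arrays the exact permutation p of the adipocyte list means was 0.257. Over the list alone, Adipoq, Cd36, Cidec and Lpl fell without control 4, and Cidec without control 1. Cidec, a lipid droplet protein, read 175 ± 102 in controls and 74.0 ± 18.2 in knockouts (log2 fold change -0.93, SE 0.34), and Plin1 had a log2 fold change of -0.20. The adipocyte adjusted p was 0.0981 without knockout 2. Endothelial markers were lower as a set (camera adjusted p = 0.0131, adjusted p = 0.796 with an estimated correlation), with none of 15 past the list threshold. Their list mean differed by -0.06 and their median was -0.04 (exact permutation p of the list means = 0.457). The difference was -0.014 without control 3, -0.10 without control 2 and -0.09 without knockout 1, and Emcn fell over the list alone without control 2 or control 4. Emcn read 305 ± 49.7 and 199 ± 32.3 (-0.58, SE 0.16), while Vwf was at 0.41. Emcn ranged from -0.65 to -0.44 with each array left out, and Vwf from 0.19 (without knockout 1) to 0.56 (without knockout 3). The endothelial adjusted p was 0.0896 without control 3 and 0.0981 without knockout 2.

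Secreted factors that act on muscle were lower as a set (camera adjusted p = 0.0181, adjusted p = 0.332 with an estimated correlation), with 10 members below and 8 above 0 and none of 18 past the list threshold. Their list mean differed by -0.09 and their median was -0.01 (exact permutation p of the list means = 0.314). Without control 1 the difference was -0.05, and without control 2, Bmp2, Bmp4 and Igf2 fell over the list alone. Bmp2 read 125 ± 44.2 in controls and 73.0 ± 3.62 in knockouts (log2 fold change -0.62, SE 0.20). Bmp4 (-0.57) and Igf2 (-0.44) were lower and Wnt3a higher (0.32), none past the threshold. The adjusted p was 0.0549 without control 1, 0.160 without control 4 and 0.0694 without knockout 2. Myogenic regulators did not pass as a set (9 members, median 0.06, camera adjusted p = 0.239, and 0.0369 without control 2). Mef2c, also a regulator of Sost, had a log2 fold change of -0.58, and Myod1 one of 0.18, and Mef2c fell over the list alone without control 2 or control 4. Mef2c ranged from -0.69 to -0.40 and Myod1 from 0.07 to 0.27 with each array left out. Skeletal muscle fibre genes (10 members, median 0.01, adjusted p = 0.519) did not pass, nor did osteoclast (14 members, median 0.09, adjusted p = 0.914) or chondrocyte markers (10 members, median 0.18, adjusted p = 0.773). Tnni2 (0.21), Ocstamp (0.32) and Comp (-0.82) had the smallest p of these 3. With each array left out they ranged from 0.15 to 0.31, 0.25 to 0.38 and -1.14 to -0.49, in this order. Camera pointed down for the myogenic and muscle fibre lists, whose medians were above 0.

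Genes next to Mbtps1 were compared with the rest, because a targeted locus can carry flanking sequence of another strain. Distance was taken between gene midpoints in GRCm38.p6. Within 10 Mb of Mbtps1, 8 of 159 genes (5.03%) had an unadjusted p under 0.05, against 892 of 13730 (6.50%) elsewhere. The odds ratio was 0.763 (two-sided Fisher exact p = 0.625). Whether the littermate controls carried the same targeted allele is not stated here. If they did, flanking sequence would not differ between the groups, so the comparison does not decide the point.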

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

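Of the tests in this part, the count of splits for the number of gene lists was chosen before the result was seen. Setting the 1.5-fold count against other splits was planned, but how to read it was written after the result was seen. All other tests were chosen after their results were seen.

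A gap test for a single far array (gap to the nearest array over the range of the group) was run on 138 groups of 4 control values, and chance passes about 1 in 20. It marked 5, of which 4 were in control 4. Lpl read 232 in control 4 (gap ratio 0.978). Ube2c read 864 (0.872), Kel 304 (0.849) and Trim10 254 (0.836) in control 4. Foxe3 read 48.7 in control 2 (0.849).

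Other splits of the 7 arrays into 4 and 3 were counted, 35 with the real one. The real split gave 0 genes at the adjusted threshold and the highest other gave 3; with a count of 0 all 35 splits give as many by construction, so this decides nothing. At unadjusted p with a 1.5-fold minimum, 8 of the 35 splits gave at least the 120 genes of the real one, and the highest other gave 189. For the gene lists, 18 of the 35 gave at least 10 called lists, and the highest other gave 15. Chance is not excluded for the last 2 counts, and a camera call with the preset correlation was frequent in splits that do not follow genotype. By single list, a p as small came from 2 of 35 splits for osteocyte markers, 3 for immediate early genes, 5 each for the S1P pathway, osteoblast and secreted factor lists, 6 for endothelial, 8 each for adipocyte and interferon lists, 18 for B cell and 34 for cell cycle genes.

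Osteocyte markers were lower in knockout bone by -0.67 in the list mean. Scaling between arrays is argued against, since after quantile normalization the difference was -0.70 and the highest knockout (8.25) lay under the lowest control (8.47). Control 4 alone is argued against too, with a difference of -0.46 without it against a larger group SD of 0.14 (exact p = 0.10, the smallest that 3 against 3 allow). A smaller share of osteocytes, which raises other cell types alike, stays open: B cell minus neutrophil means differed by 0.25 (exact p = 0.257), and of 55 pairs of other cell types 4, all with adipocyte markers, had groups apart (megakaryocyte -0.50, B cell -0.49, erythroid -0.44, T and NK -0.34), with a smallest exact p of 0.0286, or 0.786 adjusted. Tnfsf11 (0.39) and Fgf23 (0.34), 2 of the 13 members, rose over the list alone without control 4, and lower expression of the others per osteocyte may also be the source, which was not tested.

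The immediate early and heat shock list was lower by -0.59, and its 15 members other than the heat shock genes by -0.70. A single array as the cause is argued against, since the list difference was between -0.71 and -0.51 with each array left out, against group SDs of at most 0.30. Handling or digestion that differed between preparations stays open: the 3 heat shock members differed by -0.051 (exact p = 0.80), and the labels give no preparation day. A smaller share of osteocytes stays open as well, with a within-group correlation of 0.62 between both list means (exact p = 0.222 over 144 permutations). An effect of genotype could not be separated from these.

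B cell and cell cycle genes were higher as sets, with adjusted p of 0.809 and 0.949 with an estimated correlation. Control 4 alone may account for this: without it the B cell difference went from 0.28 to 0.090, the cell cycle difference from 0.18 to -0.01 and the erythroid difference from 0.23 to -0.01. More marrow left on knockout bone stays undecided, since neutrophil markers differed by 0.027 (exact p = 0.686) and macrophage markers by -0.003. A genotype effect on these cells was not tested separately.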

How the results depend on the processing

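Chosen after seeing the data were the sets without controls 3 and 4, the first principal component as a covariate, unmoderated variances, and both counts of list members; all other alternatives were planned. Values for lists are adjusted p. With camera at the preset correlation, the S1P, osteocyte, osteoblast and immediate early lists kept direction and side of the threshold in every setting. None of them passed with the estimated correlation or fry, and unmoderated variances were applied to genes only. The preset was 0.01 and the estimates were 0.11 (S1P), 0.63 (osteocyte), 0.39 (osteoblast) and 0.32 (immediate early), so this agreement does not test the preset. At unadjusted p the preset called them in 8, 29, 22 and 24 of the 35 splits. The number of arrays and the signal over background limit precision. The cause was not tested for any value below, except that leaving out arrays lowers their number and that a replicate block takes out control 4. The offset of 16 is the main setting, so it was not run again, and C2cd4b was not tested at the 50th percentile.

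Without a filter the cholesterol and fatty acid lists reversed (both 0.936), and cell cycle (0.0667) and interferon (0.0941) no longer passed. At the 50th percentile fatty acid (0.599) and osteoclast (0.725) reversed, interferon was 0.0945 and erythroid passed (0.0464). Without an offset cell cycle was 0.0588 and interferon 0.0504. With an offset of 64 the 1.5-fold count was 77 and interferon 0.0537. With quantile normalization ER stress (0.905) and neutrophil (0.227) reversed, interferon was 0.0843, and erythroid and megakaryocyte markers passed (each 0.00986), for 11 lists. Median centring and robust variance each gave 1 changed gene. Averaging probe sets reversed fatty acid (0.859).

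Array weights gave 5 changed genes and 6 lists, with Adgre1 at -0.015, cholesterol (0.438) and fatty acid (0.852) reversed, secreted 0.0835, cell cycle 0.744, interferon 0.128, B cell 0.298 and endothelial 0.0730 no longer passing, and macrophage passing as lower (0.0246). A replicate block, although replicate numbers did not pair the arrays (correlations 0.07, 0.15 and -0.53), gave 62 genes and 6 lists, with Adgre1 -0.030. Only control 4 carries its replicate number, so the block fits it exactly and the fold changes are those without control 4. This fit leaves 2 residual degrees of freedom. It reversed cholesterol (0.137), fatty acid (0.462), muscle fibre (0.577), myogenic (0.908), erythroid (0.521) and cell cycle (0.361), and left secreted at 0.122, interferon at 0.0801, B cell at 0.280 and endothelial at 0.0593, with macrophage passing as lower (0.0291). A muscle covariate gave 1 gene, fatty acid reversed (0.947) and interferon 0.111. An erythroid covariate gave 4 genes and 6 lists, with Adgre1 -0.012, cholesterol (0.204), fatty acid, muscle and erythroid (each 0.527) and cell cycle (0.512) reversed, secreted 0.187, interferon 0.110, B cell 0.365. The erythroid list's value there is fixed by construction, since its own mean is the covariate.

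With an estimated correlation 0 lists passed: S1P and secreted 0.332, cell cycle 0.949, immediate early 0.231, interferon 0.796, osteocyte and osteoblast 0.332, adipocyte 0.459, B cell 0.809, endothelial 0.796. With fry 0 passed: S1P, secreted and cell cycle 0.765, immediate early 0.424, interferon, osteocyte and osteoblast 0.725, adipocyte, B cell and endothelial 0.765, and ER stress, lysosomal, muscle, neutrophil and macrophage reversed (each 0.913). Without controls 3 and 4 there were 2 changed genes, 75 at 1.5-fold and 6 lists, with gene Megf10 at 0.028, gene Adgre1 at -0.071, cholesterol (0.173), fatty acid (0.957) and cell cycle (0.883) reversed, secreted 0.0809, interferon 0.173, B cell 0.663, endothelial 0.173, and macrophage passing as lower (8.93e-04). The component covariate gave 117 genes and 6 lists, with cholesterol (0.737) and fatty acid (0.815) reversed, secreted 0.130, cell cycle 0.257, interferon 0.177, B cell 0.167. Unmoderated variances gave 61 genes at 1.5-fold and 0 members in both list counts.

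The count at unadjusted p (904) was 1867 with array weights, 1655 with the block, 2501 with the muscle and 2173 with the erythroid covariate, 1498 without controls 3 and 4 and 2977 with the component covariate.

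Leaving out each array in turn gave 0 to 5 changed genes, 325 to 1803 at unadjusted p and 102 to 199 at 1.5-fold. Mbtps1 ranged from -0.37 to -0.14 and Adgre1 from -0.030 to 0.22, with 5 to 12 immediate early members and 4 to 12 lists. For Mbtps1 unadjusted p sets the side, and it passed as lower in 1 of these sets. List ranges were cholesterol 0.0981 to 0.732, fatty acid 0.483 to 0.978, ER stress 0.116 to 0.938, osteoclast 0.273 to 0.887, chondrocyte 0.0934 to 0.868, muscle 0.0551 to 0.995, myogenic 0.0369 to 0.984, secreted 0.00248 to 0.160, erythroid 0.00346 to 0.556, neutrophil 0.0981 to 0.949, macrophage 0.0308 to 0.925, cell cycle 0.00126 to 0.375, interferon 0.00287 to 0.2995, megakaryocyte 0.002875 to 0.754, B cell 2.45e-08 to 0.399, endothelial 0.00120 to 0.0981, adipocyte 6.04e-05 to 0.0981. The share lower at 1.5-fold was 94.2%, but 64.5% with the block, 63.2% with the erythroid covariate, 65.7% without control 4, 82.6% without control 3 and 84% without both. For odds near Mbtps1, windows of 5 and 20 Mb gave 0.485 and 0.693.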

Other observations

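All tests in this part were chosen after the data were seen.

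Among genes at an unadjusted p under 0.05, 186 were higher and 75 lower in the lowest of 4 equal bins of signal, and 45 were higher and 80 lower in the highest bin.

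A hypothesis was that the main axis of the arrays hides a genotype difference. With the first principal component as a covariate in limma, 117 genes passed the adjusted threshold, 52 lower and 65 higher. Of the 35 splits 1, the real one, gave as many, with 30 as the highest other. That is the smallest share 35 splits can give, only 25 splits had a correlation with the component at or under 0.5, and the share takes no account of the choice of this fit, so it does not exclude chance. Among the 117 were 7 osteocyte markers (Dmp1, Sost, Mepe, Phex, Dkk1, Irx5 and Ptprz1), 5 immediate early genes (Fosb, Jun, Egr1, Atf3 and Klf4), Postn and Insig2. The count was not stable: it was 1 without control 1, 235 without control 2, 0 without control 3, 0 without control 4, 1 without knockout 1, 94 without knockout 2 and 0 without knockout 3. The fit was 1 of several tried after the data were seen and leaves 4 residual degrees of freedom. It may be followed up in further animals, and it is not a result of the planned comparison.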
